A study of Mus musculus with 4 samples.

How the data were processed

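Single-nucleus RNA sequencing (10x Genomics 3′ chemistry, NovaSeq) was read from whole hearts of mice at postnatal day 12. The mice had been injected at postnatal day 7 with saline (control) or with AAV9-cTnT-YAP5SA, an adeno-associated virus in which the cardiac troponin T promoter drives an active form of the transcriptional co-activator YAP. Their mothers were on chow or on a high-fat diet (HFD) for 5 days. The 4 libraries formed 4 groups of 1 library each: control on chow, YAP5SA on chow, control on HFD and YAP5SA on HFD. How many hearts went into each library is not given in the sources used here. The control was saline, so the virus itself and its YAP5SA cargo cannot be separated in these comparisons.

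Groups were taken from the sample titles and descriptions. For 2 libraries the treatment label names the other diet: that of YAP5SA on chow names the maternal high-fat diet, and that of control on HFD names chow. The split into control and YAP5SA is the same in every label, while every diet contrast, and the diet named for each YAP5SA contrast, rests on the titles. If the treatment labels hold instead, both control libraries were on chow and both YAP5SA libraries on HFD. Vector and diet would then change together in every YAP5SA contrast, including the one that was tested.

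Per the labels, the authors aligned the reads to mm10 with Cell Ranger 7.1.0. The deposited matrices hold counts, namely raw UMI counts per gene and nucleus for the barcodes the authors kept, with no normalization. The gene annotation and the use of intronic reads are not given in the sources used here. The matrices list 32291 features, of which 6 are added sequences that are not mouse genes. Coordinates (mm10) were joined by Ensembl identifier from the GENCODE vM21 annotation, which holds 32158 of the identifiers.

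Nuclei with fewer than 500 genes or more than 5% mitochondrial UMIs were removed. Doublets were then called per library with Scrublet as implemented in scanpy 1.11.5 (Python 3.11.15). Where its automatic threshold marked under 0.5% of nuclei, the top scores at a rate of 0.8% per 1000 nuclei were removed instead. That rule applied to control on chow, where the threshold marked 0.141%. The doublet share removed was 5.10% in control on chow, 5.23% in YAP5SA on chow, 5.44% in control on HFD and 8.50% in YAP5SA on HFD. The filter removed 604, 699, 748 and 432 barcodes in the same order, and 32018 nuclei were kept. Counts were log-normalised, 3000 variable genes and 30 principal components were taken without Xist, Tsix, named Y-linked genes, the added sequence nsp13 and mitochondrial genes, and nuclei were clustered with the Leiden algorithm over the 4 libraries together, without integration (igraph 0.11.9, 15 neighbours, resolution 1, seed 0), which gave 27 clusters.

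Clusters were named from marker lists of 19 cell types fixed before any count was seen. A marker counted as present where at least 10% of a cluster's nuclei held it and its CPM reached 0.25 of its highest cluster value. The type with the largest share of its markers present named the cluster if that share was at least 0.5 and at least 3 markers were present. A cluster stayed unnamed where several of its 10 top genes were markers of, or peaked in, an unrelated class. These limits were set after the data were seen. Cluster 17 was kept out by the last of them, with 3.24%, 2.96%, 5.71% and 2.52% of nuclei in control on chow, YAP5SA on chow, control on HFD and YAP5SA on HFD. Clusters 20 and 16 were also kept out, with 1.37%, 2.11%, 1.81% and 0.927% for cluster 20 and 0.0165%, 0%, 0.378% and 0.0102% for cluster 16. Class names carry "-like" because they rest on markers alone. Of the 27 clusters, 10 were cardiomyocyte-like, including an atrial cluster.

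For each class and library the UMIs of all nuclei were summed and scaled to CPM, UMIs per 1e6 UMIs of the sum. Each YAP5SA contrast within a diet and each diet contrast within control or YAP5SA compared 1 library with 1 library, so no test was made. A log2 fold used a prior of 0.5 counts and carries an exact 95% interval from the conditional binomial distribution (scipy 1.17.1). Shares carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only, not the difference between animals. An overlap of separate intervals does not show that the values are equal. Genes with a mean CPM of at least 10 over the 4 sums were compared, and genes at least 2-fold apart were counted. Where a gene had 0 counts in a library, the interval of its fold had no bound on that side. Class contrasts were limited to classes with at least 200 nuclei in every library, which left out macrophage-like nuclei.

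Of 29 gene lists fixed before any count was seen, holding 619 genes, each was summarised by the median log2 fold of the members at a mean CPM of at least 10. Each median was placed among those of 10000 random lists of the same size matched on mean CPM in 20 bins. A percentile above 97.5 or below 2.5 is called high or low here. It describes these libraries and is not a test. Markers of 10 other cell types were read in the cardiomyocyte-like sums in the same way as a measure of free RNA and doublets. Members of a list were counted as higher or lower at 1.5-fold.

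The one contrast that was tested compared YAP5SA with control over both diets on the cardiomyocyte-like sums, 2 libraries per arm. HFD against chow over control and YAP5SA together, and YAP5SA against control in other classes, were not tested in this way. It used edgeR 4.0.16 (R 4.3.3) with TMM, filterByExpr, glmQLFit and glmQLFTest, the design of vector alone and Benjamini-Hochberg adjustment, with a threshold of 0.05. By the titles, its replicates are the libraries of the different diets, so the difference between diets counts as spread. Under the treatment labels, diet would instead be aligned with the vector and would not enter the spread. The YAP5SA arm held a male and a female library and the control arm only female ones. Sex therefore also enters the spread and is partly aligned with the vector. Only genes past this threshold are said to have risen or fallen.

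For the cell cycle, each nucleus was thinned to 1000 UMIs, shallower nuclei were left out, and nuclei with UMIs of at least 2 genes of the G2/M list were counted.

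Genes were named by a rule fixed before any count was seen, which excludes predicted genes, mitochondrial and ribosomal transcripts, Xist and Y-linked genes from ranks. From the YAP5SA contrasts, the 12 highest and 12 lowest genes were taken by the smaller of their log2 folds, among genes at a mean CPM of at least 50 and at least 2-fold apart in the same direction on both diets. Each diet contrast gave its 6 highest and 6 lowest genes among those at least 1.5-fold apart, and the difference between the YAP5SA folds gave its 5 highest and 5 lowest. Each list gave its 2 highest and 2 lowest members by the mean of the YAP5SA folds and by the mean of the diet folds. Fibroblast-like and endothelial-like sums gave their 4 highest and 4 lowest among genes at a higher CPM there than in cardiomyocyte-like sums. Yap1, Ccn1, Ccn2, Ankrd1, Myh6, Myh7, Cpt1b and Pdk4 were always named, with Xist and Ddx3y as a check of sex. Members of the lists read in other classes, and genes said to be so, were chosen after their values were seen. Results of some genes that the rule names, and what the alternatives did to them, are not reported here.

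Both procedures were tested on simulated data. In simulated pairs of libraries, 2 of 50 genes set 1.5-fold apart and 50 of 50 set 3-fold apart passed the 2-fold mark, and the 95% intervals covered the true fold of 95.1% of unchanged genes for chow and 95.7% for HFD. Of 200 unshifted lists, 8 lay outside the band of percentiles. These pairs were drawn with Poisson counting error alone, which the intervals assume, so coverage near 95% was built in. Genes were drawn independently, so the list result does not extend to lists of co-regulated genes. For edgeR with 2 libraries per arm, 5 of 50 genes changed 2-fold, 45 of 50 changed 4-fold and 49 of 50 changed 8-fold were called, beside 8 unchanged genes. That simulation gave every gene the same dispersion (0.0562) and put no difference of diet or sex between libraries.

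The alternatives tried were stricter and looser nucleus filters, doublets kept, a resolution of 2, and TMM or DESeq2 (1.42.0) scaling of the sums. Further alternatives were equal weight for each nucleus, thinning, other CPM floors, a 1.5-fold mark, no atrial cluster and totals without mitochondrial transcripts. For the test they were a DESeq2 Wald test, other normalizations, no filter on low counts, diet as a block and leaving out each library. The class contrasts were repeated with TMM and without genes higher in cardiomyocyte-like sums. Leaving out genes on the X and Y chromosomes and leaving out cluster 5 were chosen after seeing the data.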

Results

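Nuclei from whole hearts of mice at postnatal day 12 were profiled in 4 libraries: control on chow, YAP5SA on chow, control on a maternal high-fat diet (HFD) and YAP5SA on HFD, with 1 library per group and so no replicates. The series concerns YAP, the transcriptional co-activator held in check by the Hippo pathway, and the use of fuels by cardiomyocyte mitochondria. The libraries held 6977, 9368, 9145 and 11158 barcodes in that order and 43.4, 51.7, 57.5 and 61.2 × 1e6 UMIs. After filtering, 6048, 8216, 7940 and 9814 nuclei remained, with medians of 5045, 4350.5, 4843 and 4118 UMIs and of 2246.5, 2013, 2227 and 2056 genes per nucleus. The median share of mitochondrial UMIs was 0.163%, 0.147%, 0.220% and 0.107%. Xist, expressed from the inactive X chromosome of females, had 92725, 280, 126376 and 125624 UMIs, and the Y-linked gene Ddx3y 0, 4159, 15 and 14, so the chow contrast of YAP5SA set a male library against a female one. Where values of all 4 libraries are listed, they follow this order.

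Cardiomyocyte-like nuclei made up 58.6% of nuclei in control on chow (95% interval 57.3% to 59.8%), 58.5% in YAP5SA on chow (57.4% to 59.5%), 37.9% in control on HFD (36.9% to 39.0%) and 51.3% in YAP5SA on HFD (50.3% to 52.3%). With stricter nucleus filters they made up 70.7%, 58.0%, 49.7% and 52.6%, so the shares on chow moved apart and the gap on HFD narrowed. A finer clustering gave 47.6% in YAP5SA on chow. Fibroblast-like nuclei made up 18.1%, 15.3%, 27.1% and 23.3%. Macrophage-like nuclei made up 1.93% (1.60% to 2.31%), 2.58% (2.25% to 2.95%), 2.59% (2.26% to 2.97%) and 5.45% (5.01% to 5.92%), so their share was highest in YAP5SA on HFD. With a looser filter and with a finer clustering the share in YAP5SA on chow was 1.29%, below control on chow (1.64% and 1.70%), and with stricter filters it was 1.84% against 2.06%. Endothelial-like nuclei made up 6.71%, 4.69%, 7.70% and 4.05%, endocardial-like nuclei 3.89%, 7.39%, 7.38% and 6.19%, and epicardial-like nuclei 1.82%, 3.64%, 3.88% and 1.80%. With stricter filters, endothelial-like nuclei made up 2.16%, 2.30%, 3.17% and 2.49% and endocardial-like nuclei 0.748%, 2.21%, 2.08% and 1.93%, so the order of the endothelial-like shares on chow turned. Those filters allow at most 1% mitochondrial UMIs, while the median was 1.47% in endothelial-like cluster 13 and 2.32% in the endocardial-like cluster. They therefore remove such nuclei by choice of limit. In control on chow they left 107 of 406 endothelial-like nuclei, against 3497 cardiomyocyte-like nuclei where 3543 stood before. Pericyte-like nuclei made up 2.74%, 1.57%, 2.88% and 2.51%, and the atrial cluster among the cardiomyocyte-like nuclei 0.231%, 0.962%, 1.06% and 1.90%. Smooth muscle, lymphocyte, lymphatic endothelial and Schwann cell classes each held 1.34% or less of every library. Shares of nuclei also depend on how well each cell type's nuclei were released and kept, and the share of unnamed nuclei ranged from 3.45% in YAP5SA on HFD to 7.90% in control on HFD.

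**Figure D1:**
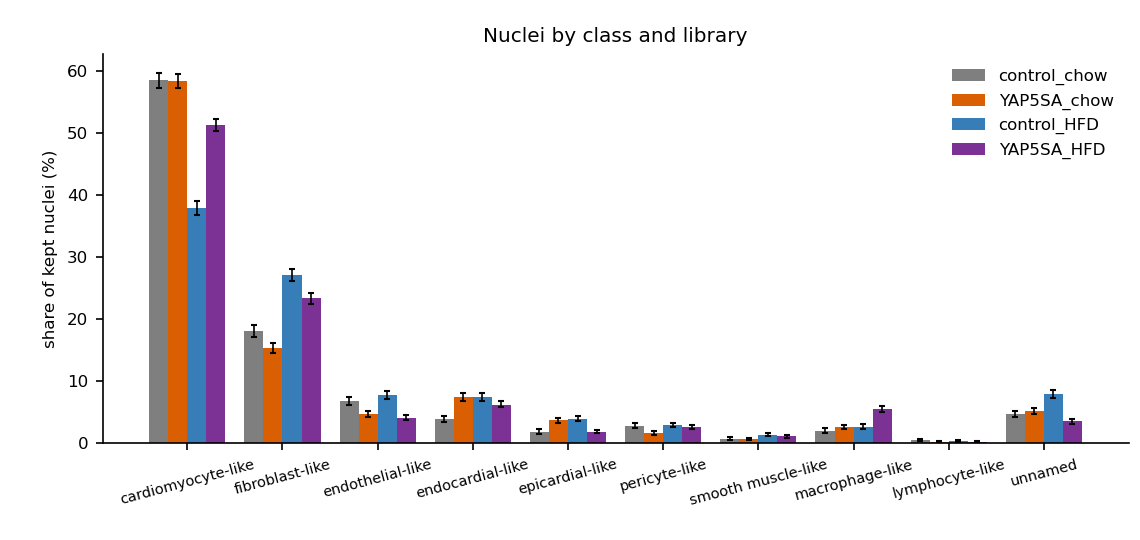
Share of kept nuclei (percent) in the main cell classes and unnamed, per library, with exact 95% intervals for counting error. The cardiomyocyte-like share is lowest in control on HFD (37.9%) and the macrophage-like share is highest in YAP5SA on HFD (5.45%).

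The cardiomyocyte-like nuclei of control and YAP5SA libraries fell largely into different clusters. Clusters 5 and 24 held 33.3% and 21.6% of them in YAP5SA on chow and 17.7% and 15.6% in YAP5SA on HFD, against 0% and 0.0282% in control on chow and 0% and 0.0664% in control on HFD. Clusters 6 and 7 held 48.9% and 20.3% in control on chow and 30.3% and 44.5% in control on HFD, against 7.37% and 1.83% in YAP5SA on chow and 3.52% and 2.05% in YAP5SA on HFD. Cluster 10 held 15.8%, 8.70%, 5.58% and 35.2%. Cluster 5 carried 7 of 14 cardiomyocyte markers by the naming rule. Ttn, the giant sarcomere protein titin, was found in 99.4% of its nuclei at a CPM of 5856, against 442 CPM in endothelial-like nuclei. Myh6 stood at 316 CPM there, against 4623 in cardiomyocyte-like nuclei outside cluster 5 and 271 in endothelial-like nuclei, and Tnni3 at 55.6 against 309 and 66.8. With stricter nucleus filters 53.4% of the nuclei of cluster 5 were left unnamed, and 53.7% with a finer clustering. The cardiomyocyte values below are sums over all of these clusters.

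The first question was what YAP5SA changed in cardiomyocytes. Transcripts of Yap1 itself (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) stood at 136, 107, 128 and 120 CPM, a log2 fold of −0.34 on chow and −0.09 on HFD. A 3′ read need not capture the transgene, whose sequence is not among the mouse genes. Established YAP targets were far higher in YAP5SA. Ccn1, a matricellular protein gene (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), stood at 10.0, 184, 13.2 and 75.9 CPM, a log2 fold of 4.19 on chow (95% interval 4.01 to 4.39) and 2.52 on HFD (2.34 to 2.71). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) stood at 33.8, 356, 39.8 and 163 CPM, or 3.40 on chow and 2.04 on HFD. Ankrd1, which encodes a cardiac ankyrin repeat protein, stood at 1117, 3148, 985 and 1882 CPM, or 1.49 and 0.93. Of 16 measured YAP target genes, 12 were at least 1.5-fold higher on both diets and 0 were lower on both, and the median log2 fold was 2.15 on chow (percentile 100 among matched random lists) and 1.51 on HFD (percentile 100). Without cluster 5 these medians were 1.24 and 0.73. Within clusters 6, 7, 8, 9 and 10, which hold nuclei of every library, they were 0.28, 0.30, 0.48, −0.04 and 0.14 on chow and 0.41, 0.37, 0.71, −0.05 and 0.14 on HFD, and within cluster 4 they were 2.83 and 2.12. The values of the sums thus also follow which clusters the nuclei of each library fell into, and the clusters were themselves drawn from expression.

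Among the genes furthest above control on both diets, Cemip, a hyaluronan-degrading protein gene (ENSMUSG00000052353, chromosome 7, 83932857 to 84086502), stood at 2.23, 995, 1.95 and 763 CPM, a log2 fold of 8.79 on chow (8.41 to 9.22) and 8.59 on HFD (8.17 to 9.10). Ptchd4 was higher by 8.32 and 8.78, the semaphorin gene Sema3e by 7.98 and 8.15, and the collagen gene Col12a1 by 7.69 and 7.16. The TEAD cofactor gene Vgll3 was higher by 8.25 and 7.12, and Wwc1, which encodes the Hippo pathway protein KIBRA, by 7.28 and 6.32. Hs6st2, Col8a1, Col4a3, Plcxd2, Pak3 and Col4a4 had log2 folds between 5.79 and 6.76 on chow and between 4.78 and 6.06 on HFD.

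Among the genes furthest below control on both diets, Ppara, which encodes the fatty acid sensing nuclear receptor (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819), stood at 300 CPM in control on chow, 90.6 in YAP5SA on chow, 449 in control on HFD and 105 in YAP5SA on HFD, a log2 fold of −1.72 (−1.79 to −1.66) and −2.10 (−2.16 to −2.04). The phosphodiesterase gene Pde4d stood at −2.42 and −1.81, and Ckm, which encodes the muscle creatine kinase, at −1.84 and −1.90. Hopx, a cardiac homeodomain gene, stood at −1.56 and −2.72, and the potassium channel gene Kcnn2 at −1.71 and −1.62. Plekhh1, Hs3st5, Ush1c, Sbk1, Yipf7, Ank1 and Inka2 had log2 folds between −3.42 and −1.58 on chow and between −3.35 and −1.70 on HFD.

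Across 8466 genes, 724 were at least 2-fold higher and 597 at least 2-fold lower in YAP5SA on chow, and 913 and 308 on HFD. Without cluster 5 the counts on chow were 433 and 234, and 361 and 364 were lower with stricter nucleus filters and with a finer clustering. On both diets 494 were higher and 161 lower, where 78.1 and 21.7 would be shared if the contrasts were independent, and 19 lay 2-fold apart in opposite directions. The log2 folds of the contrasts, which share no library, had a Pearson r of 0.757 and a Spearman rho of 0.653 across genes, which are not independent replicates. Of the genes 2-fold apart on HFD, 74.8% were higher, against 59.1% with TMM and 54.3% with DESeq2 scaling, which move the median log2 fold of all genes from 0.12 to −0.06 and −0.11. On chow 54.8% were higher, and 56.9% and 58.0% with those scalings.

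**Figure D2:**
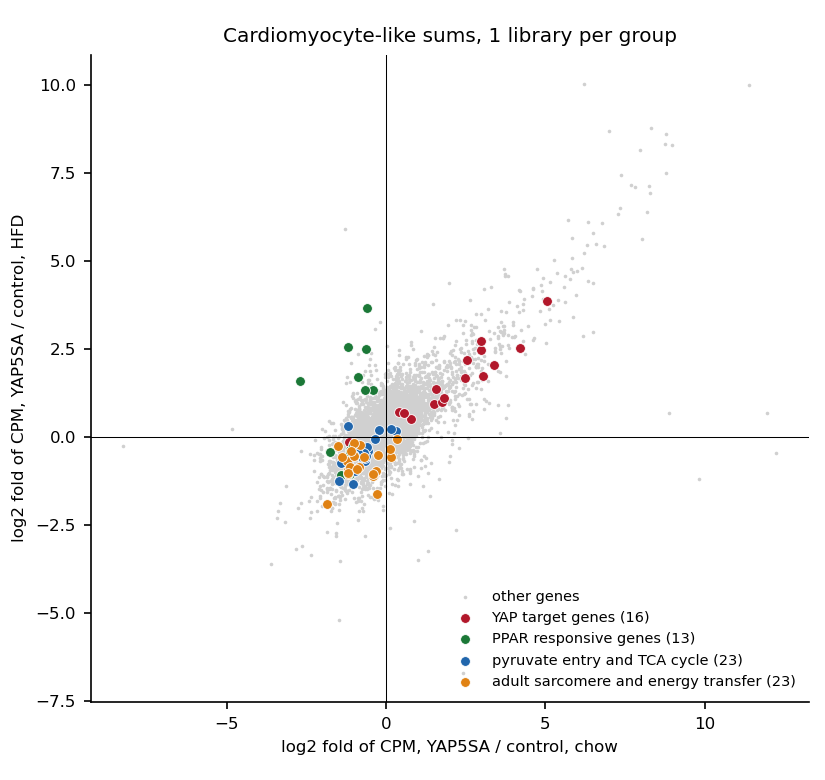
Log2 fold of YAP5SA over control in cardiomyocyte-like sums for each gene, on chow (horizontal axis) and on HFD (vertical axis), with members of 4 gene lists in colour. Most genes far from 0 lie in the same direction on both diets (494 higher and 161 lower at 2-fold, 19 opposite).

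With both diets together, 2 libraries per arm, 1316 of 16877 genes rose and 698 fell in YAP5SA (edgeR). These counts were 787 and 340 with stricter nucleus filters and 751 and 353 with a finer clustering, and 1149 fell in a DESeq2 Wald test. The only male library was in the YAP5SA arm, so sex is partly aligned with the vector in this test. Under the treatment labels, diet would be fully aligned with the vector. All 24 genes named above as furthest from control were among the edgeR calls, which is no separate evidence, as they were picked by their folds in the same libraries. Among the YAP targets, Myof rose with a log2 fold of 4.35 (SE 0.37, adjusted p = 0.00237), Crim1 with 2.78 (SE 0.19, adjusted p = 0.00163) and Ccn2 with 2.77 (SE 0.42, adjusted p = 0.0122). Ankrd1 stood at 1.21 (SE 0.31, adjusted p = 0.0545) and Yap1 at −0.29 (SE 0.15, adjusted p = 0.268), neither past the threshold. Of 20 YAP target genes tested, 12 rose and 0 fell, and 15 rose and 1 fell adjusted over the list alone. Of 21 Hippo pathway components, 9 rose and 0 fell (12 and 1 adjusted over the list alone), and their median log2 folds were 0.90 on chow and 0.61 on HFD. Without control on HFD 362 genes fell, in proportion the largest move on leaving out a library.

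In each list of cell skeleton, matrix and secreted factor genes, more rose than fell in YAP5SA cardiomyocyte-like sums. The cytoskeleton and adhesion list had medians of 0.63 on chow (percentile 100) and 0.26 on HFD (percentile 98.4), and 10 of 36 genes tested rose and 0 fell (13 and 1 adjusted over the list alone). The tropomyosin gene Tpm4 rose with a log2 fold of 2.39 (SE 0.24, adjusted p = 0.00389). The extracellular matrix list had medians of 0.70 (percentile 100) and 0.29 (percentile 88.7), and 5 of 26 genes rose and 2 fell (5 and 3 adjusted over the list alone). Thbs1 was higher by 5.63 on chow and 3.82 on HFD, while the laminin gene Lamb1 stood at −1.23 and −0.99. Fibroblast markers in the same sums had medians of −0.25 and −0.74, and 1 of 9 fell and 0 rose (1 rose and 3 fell adjusted over the list alone).

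The growth factor and insulin signalling list had medians of 0.39 (percentile 99.8) and 0.38 (percentile 99.0), the latter turning to −0.0253 at a mean CPM of at least 50, and 6 of 28 genes rose and 1 fell (9 and 4 adjusted over the list alone). Tgfb3 was higher by 5.98 and 4.03 and Bmp4 by 2.65 and 3.88, while Vegfa, the endothelial growth factor gene, stood at −0.78 and −1.03. Of 17 complement, chemokine and colony-stimulating factor genes tested, 7 rose and 0 fell (8 and 0 adjusted over the list alone). Csf1, the macrophage growth factor gene, stood at 14.7, 62.6, 13.2 and 72.7 CPM and rose with a log2 fold of 2.20 (SE 0.17, adjusted p = 0.00205). The 3 members measured at the CPM floor had medians of 0.80 and 1.01. Macrophage markers were also higher in these sums, where 2 of 9 rose and 0 fell (4 and 0 adjusted over the list alone), among them Lyz2 with 1.93 (SE 0.40, adjusted p = 0.0308).

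Genes of hypoxia and p53 responses were mixed. Hypoxia responsive genes had medians of 0.08 and 0.16, and 3 of 16 rose and 1 fell (4 and 1 adjusted over the list alone). P4ha1, a collagen prolyl hydroxylase gene, was higher by 2.70 and 2.21 and the glucose transporter gene Slc2a1 by 3.69 and 2.95. Apoptosis and p53 targets had medians of −0.11 and 0.44, and 1 of 13 rose and 0 fell (4 and 0 adjusted over the list alone), with the death receptor gene Fas higher by 2.43 and 1.37.

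Mitochondrial energy genes were lower in YAP5SA cardiomyocyte-like nuclei. The pyruvate entry and TCA cycle list had medians of −0.73 (percentile 0) on chow and −0.50 (percentile 0) on HFD, and 12 of 25 genes fell and 0 rose (18 and 0 adjusted over the list alone). Mpc1, which encodes a subunit of the mitochondrial pyruvate carrier, fell by 1.42 (SE 0.16, adjusted p = 0.00510), and Ogdh fell by 1.30 (SE 0.24, adjusted p = 0.0232). Nuclear-encoded oxidative phosphorylation genes had medians of −0.70 (percentile 0) and −0.40 (percentile 0), and 19 of 55 fell and 0 rose (44 and 0 adjusted over the list alone), among them Sdhb and Cox7b. Mitochondrial biogenesis regulators had medians of −0.81 (percentile 0.01) and −0.61 (percentile 0), and 6 of 17 fell and 0 rose (10 and 0 adjusted over the list alone). Mitochondrial dynamics and mitophagy genes had medians of −0.47 (percentile 2.39) and −0.26 (percentile 1.72), and 3 of 14 fell and 0 rose (4 and 0 adjusted over the list alone), with Mfn1 among them. The 13 transcripts encoded by the mitochondrial genome did not pass the test, over all genes or adjusted over the list alone, with medians of −0.12 and −0.27.

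Fatty acid genes were lower in YAP5SA on chow, but not as a list on HFD. Of 23 genes of fatty acid uptake and oxidation, 22 were at least 1.5-fold lower on chow, where the median log2 fold was −1.03 (percentile 0), or −0.63 without cluster 5. On HFD 3 were lower and 3 higher, with a median of −0.04 (percentile 21.8). Cpt1b, the gate of fatty acid entry into muscle mitochondria (ENSMUSG00000078937, chromosome 15, 89416405 to 89425863), stood at 176, 61.5, 157 and 68.8 CPM and was lower on both diets, by a log2 fold of −1.51 (−1.60 to −1.43) and −1.19 (−1.27 to −1.11). It was among 4 of 23 genes that fell, while 0 rose (4 and 0 adjusted over the list alone). Slc27a1, a fatty acid transporter gene, stood at −2.04 and −0.34 and did not pass (adjusted p = 0.10002).

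Other fuel pathways lay in mixed directions. Glycolysis and glucose uptake genes had medians of −0.13 (percentile 28.9) and −0.29 (percentile 0.08), and 1 of 24 rose and 4 fell (1 and 8 adjusted over the list alone). Slc2a1 rose with a log2 fold of 3.44 (SE 0.62, adjusted p = 0.0208) and Pfkfb2 fell by 1.70 (SE 0.24, adjusted p = 0.00992). None of 8 pentose phosphate pathway genes passed, over all genes or adjusted over the list alone, with medians of −0.10 and 0.33. Of 18 branched-chain amino acid catabolism genes 2 fell and 0 rose (1 and 0 adjusted over the list alone), with medians of −0.39 (percentile 2.41) and −0.00 (percentile 14.5). Of 3 ketone body genes 0 passed (0 rose and 2 fell adjusted over the list alone), with medians of −0.54 and −0.72. Serine, one-carbon and glutamine genes had medians of −0.06 and 0.43, and 3 of 21 rose and 2 fell (7 and 2 adjusted over the list alone), with Got1 and Got2 among those that fell. Lipid and cholesterol synthesis genes had medians of 0.50 (percentile 98.9) on chow and −0.44 (percentile 0.13) on HFD, and 1 of 18 fell, namely Acacb (1 adjusted over the list alone), and 0 rose. The 5 integrated stress response genes at the CPM floor had medians of −0.15 and −0.44 (percentile 1.77). With no floor the latter turned to 0.69, the median log2 fold over the 13 genes tested was 1.05, and 1 of 13 rose and 2 fell (5 and 2 adjusted over the list alone).

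Contractile and ion handling genes were lower in YAP5SA. The adult sarcomere and energy transfer list had medians of −0.92 (percentile 0) and −0.68 (percentile 0), and 10 of 23 fell and 0 rose (16 and 0 adjusted over the list alone). Myh6, the adult mouse cardiac myosin heavy chain gene (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927), stood at 5567, 2432, 5634 and 2692 CPM and fell by 1.20 (SE 0.21, adjusted p = 0.0186). Cluster 5, which holds no control nuclei, had Myh6 at 316 CPM and Tnni3 at 55.6 CPM. In cardiomyocyte-like nuclei outside it these stood at 4623 and 309 CPM, so cluster make-up enters the values of the sums here too. Myh7, the fetal heavy chain gene, stood at 1164, 945, 1050 and 987 CPM (log2 fold −0.27, SE 0.18, adjusted p = 0.371). Calcium handling and ion channel genes had medians of −0.73 (percentile 0) and −0.30 (percentile 1.04), and 3 of 29 fell and 0 rose (6 and 1 adjusted over the list alone). Kcnip2, a subunit gene of the transient outward potassium channel, was 10.4-fold lower on chow and 4.31-fold lower on HFD. Fetal and stress cardiac genes had medians of 0.23 and 0.07, and 1 of 17 rose and 1 fell (4 and 3 adjusted over the list alone). The natriuretic peptide genes Nppa and Nppb were higher by 2.61 and 2.14 on chow and by 0.65 and 0.82 on HFD. Neither passed the test, with adjusted p = 0.0834 and 0.0972.

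**Figure D3:**
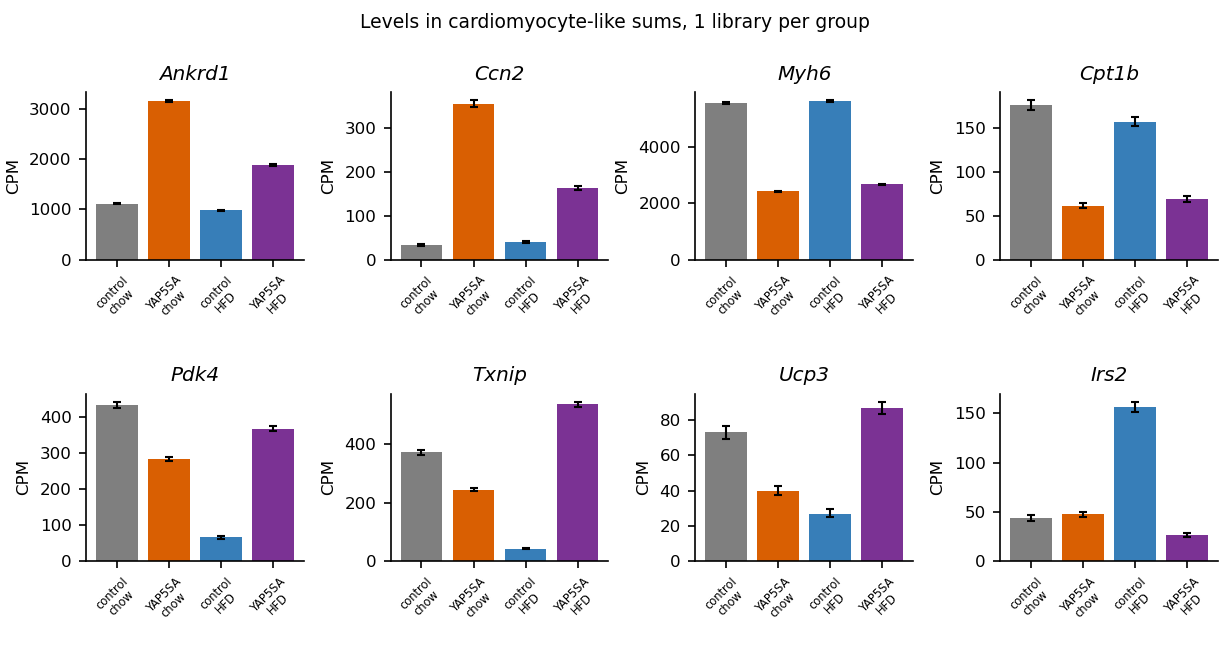
CPM of 8 named genes in the cardiomyocyte-like sum of each library, as bars from 0 with exact 95% intervals for counting error. Myh6 and Cpt1b are lower in both YAP5SA libraries, while Pdk4 and Txnip are lowest in control on HFD (65.6 and 42.3 CPM).

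The next question was whether the YAP5SA contrast has another size under HFD, for which 1 library per group gives no replicate check. PPAR responsive genes, induced when fatty acids are plentiful, had a median log2 fold of −1.12 (percentile 0) on chow and 1.32 (percentile 100) on HFD. Of 13 measured, 12 were at least 1.5-fold lower on chow, while 7 were higher and 2 lower on HFD. Within clusters 6, 7, 8, 9 and 10 the medians were −0.08, −0.62, −0.05, 0.20 and −0.24 on chow and 0.93, 1.43, 0.39, 0.55 and 1.19 on HFD, and within cluster 4 they were −1.74 and −0.02, so cluster make-up enters the chow value of the sums. Txnip, a brake on glucose uptake (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883), stood at 372, 244, 42.3 and 537 CPM, so that its log2 fold was 4.27 higher on HFD than on chow (4.17 to 4.38). Pdk4, the kinase that shuts pyruvate dehydrogenase (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), stood at 434, 283, 65.6 and 367 CPM, a difference of 3.10 (3.01 to 3.19). Ucp3, Impa2 and Neb followed, with YAP5SA log2 folds of −0.87, −1.80 and −1.08 on chow and 1.69, 0.46 and 1.16 on HFD. In the opposite direction, the log2 fold of Oser1 was 3.77 on chow and 0.52 on HFD, that of Ryr3 3.51 and 0.90, that of Gask1b 2.58 and −0.02, that of Baiap2l1 1.67 and −1.19 and that of the insulin receptor substrate gene Irs2 0.13 and −2.59. Ryr3 was among the 10 top genes of the atrial cluster, which held 14, 79, 84 and 186 nuclei. With the diets together, 4 of 17 PPAR responsive genes fell and 0 rose (6 and 0 adjusted over the list alone), among them Vldlr, Cidea and Plin4. Pdk4 (adjusted p = 0.804) and Txnip (adjusted p = 0.561) were not among them.

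Cell-cycle genes were read at equal depth. Of cardiomyocyte-like nuclei thinned to 1000 UMIs, 5.09% (4.39% to 5.87%) in control on chow, 9.004% (8.21% to 9.85%) in YAP5SA on chow, 4.02% (3.35% to 4.79%) in control on HFD and 5.40% (4.79% to 6.06%) in YAP5SA on HFD held UMIs of at least 2 G2/M genes. Without thinning, the shares were 21.5%, 27.9%, 22.3% and 24.7% at median depths of 5795, 5006.5, 6009 and 4890 UMIs. The G2/M list summed to 770, 988, 613 and 704 CPM. Diaph3, a formin gene with roles in cytokinesis, was higher by 1.85 on chow and 1.44 on HFD and rose in the test (adjusted p = 0.0273), while the median of the G2/M list was 0.15 and −0.06. Of 35 G2/M genes 1 rose and 1 fell, with 0 adjusted over the list alone. Every class held such UMIs, and among endothelial-like nuclei the share was 11.9%, 6.88%, 11.9% and 7.03%. Cluster 4, with Ect2, Anln and Top2a among its top genes, held 3.36% (2.79% to 4.01%), 5.60% (4.97% to 6.29%), 2.39% (1.88% to 3.002%) and 3.16% (2.69% to 3.68%) of cardiomyocyte-like nuclei. After thinning, 97.48% or more of its nuclei held such UMIs in every library, against 1.79%, 3.69%, 1.67% and 2.38% of those outside it. No class here is known to lack G2/M transcripts, so free RNA of cycling cells stays open as a source of these UMIs. Cluster 4 was itself drawn from these transcripts, so its gap to the other nuclei cannot say how much came from free RNA. Ect2, Anln and Top2a were chosen after they were seen.

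Genes of DNA replication had medians of 0.57 (percentile 98.9) and 0.59 (percentile 93.7) over 9 measured members, and 4.47%, 8.59%, 3.33% and 5.32% of thinned cardiomyocyte-like nuclei held at least 2 of them. Cluster 19, with the S-phase genes Hells, Dtl and Uhrf1 among its top genes, ran the other way, with 125, 16, 42 and 1 nuclei. Its top genes also held Kcnn2, named above as lower in YAP5SA, so its counts do not measure S phase alone. None of 32 DNA replication genes tested passed, over all genes or adjusted over the list alone. Of 20 cyclin, CDK inhibitor and cell-cycle exit genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with medians of −0.08 and 0.22. The gene that fell was Tbx20, a cardiac transcription factor gene (log2 fold −1.32, SE 0.29, adjusted p = 0.0380).

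**Figure D4:**
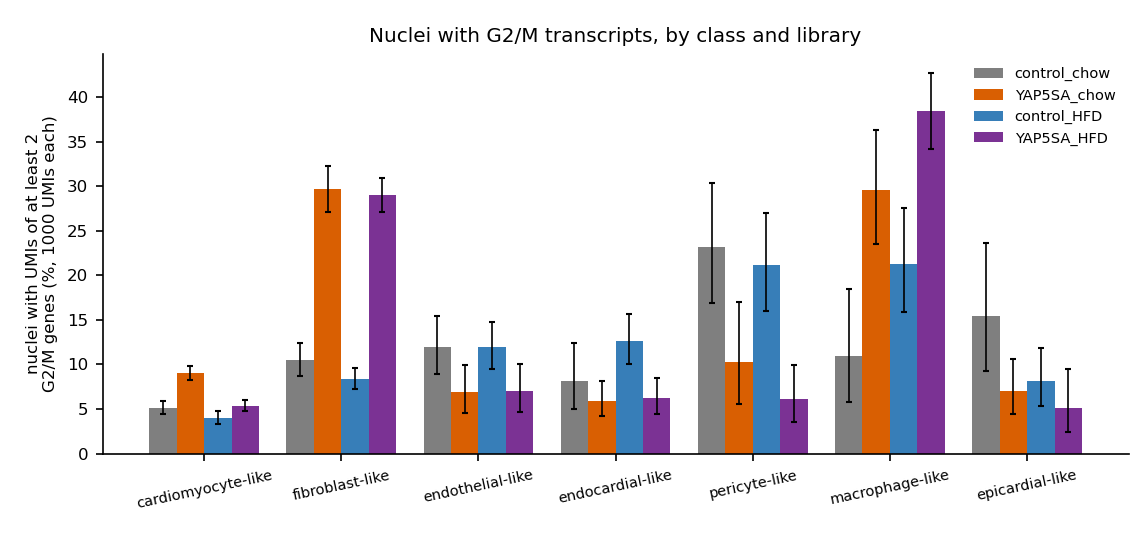
Share of nuclei (percent) with UMIs of at least 2 G2/M genes after thinning to 1000 UMIs, by cell class and library, with exact 95% intervals. In fibroblast-like nuclei the share was 29.7% and 29.0% in the YAP5SA libraries against 10.5% and 8.39% in control.

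The third question was what HFD changed in control cardiomyocytes. PPAR responsive genes were lower in control on HFD than in control on chow, with a median log2 fold of −1.02 (percentile 0). Txnip was 8.79-fold lower and Pdk4 6.62-fold lower, with Scd4, Impa2 and Ucp3 at −1.69, −1.63 and −1.44. Ptchd4 stood at −1.64 (−3.52 to −0.27) from 19 and 5 UMIs. Fatty acid uptake and oxidation genes had a median of −0.52 (percentile 0), with 10 of 23 lower and Lpl, the lipoprotein lipase gene, higher by 0.67. Irs2 was higher by 1.85, Lpin1, a phosphatidate phosphatase and coactivator gene, by 2.06, and Ppargc1a, a master regulator of mitochondrial biogenesis, by 1.49 (679 to 1900 CPM). Oser1, Ryr3, Fgf12 and Pdlim3 were higher by 3.19, 2.63, 2.47 and 2.27. Of these, Ryr3 and Fgf12 were among the 10 top genes of the atrial cluster. That cluster is part of the sums and held 14 nuclei in control on chow and 84 in control on HFD. Lipid and cholesterol synthesis genes had a median of 0.30 (percentile 99.96), with Cyp51 higher by 1.51.

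Cell-cycle lists were low in this contrast, at −0.57 (percentile 0.01) for DNA replication, −0.30 (percentile 0.06) for G2/M and −0.30 (percentile 0.19) for cyclins and cell-cycle exit. Serine, one-carbon and glutamine genes were low at −0.41 (percentile 0.01). Extracellular matrix genes were high at 0.50 (percentile 100), but stood at −0.21 at a mean CPM of at least 50, and fibroblast markers in the same sums were higher by a median of 0.43 (percentile 99.95). The YAP target, cytoskeleton and growth factor lists had small positive medians of 0.14 (percentile 99.7), 0.08 (percentile 99.6) and 0.09 (percentile 99.1). The immediate early list, which also answers to dissociation, had a median of 0.08 (percentile 94.1), with Nr4a1 higher by 3.38 (8.58 to 89.7 CPM) and Atf3 by 2.83 (4.72 to 33.8 CPM) in control on HFD. Medians of the other lists were Hippo −0.01, glycolysis −0.15, pentose phosphate −0.30, TCA cycle −0.08, oxidative phosphorylation −0.02, mitochondrially encoded −0.06 and branched-chain amino acids −0.18. Ketone body genes stood at −0.07, stress response at 0.13, biogenesis at 0.00, mitochondrial dynamics at −0.12, fetal genes at −0.01, sarcomere at 0.05, calcium handling at 0.04, complement at −0.18, hypoxia at −0.10 and p53 targets at −0.08. Over all genes, 116 were at least 2-fold higher and 58 lower.

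The fourth question was how YAP5SA cardiomyocytes on HFD differed from those on chow. This contrast also sets a female library against a male one, so sex and diet are not separated in it. PPAR responsive genes were higher on HFD, with a median of 0.61 (percentile 99.99), as were fatty acid uptake and oxidation genes at 0.60 (percentile 100), with 12 of 23 higher and 0 lower. Within clusters 4, 5, 6, 7, 8, 9, 10, 23 and 24 the PPAR medians were 0.25, 0.28, 0.05, 0.48, −0.41, 0.05, 0.26, 0.40 and 0.32. Slc27a1 was higher by 1.32 and Pdk2 by 1.33. Nuclear-encoded oxidative phosphorylation genes had a median of 0.28 (percentile 99.98), the TCA cycle list 0.22 (percentile 98.4) and calcium handling genes 0.20 (percentile 98.1). YAP targets were lower, at −0.46 (percentile 0), with Ccn1 at −1.28, Ccn2 at −1.13 and Ankrd1 at −0.74. Within clusters 4, 5, 6, 7, 8, 9, 10, 23 and 24 the medians were −0.22, −0.20, 0.24, 0.08, 0.01, −0.03, 0.06, −0.20 and −0.16. The value of the sums thus also follows how the nuclei were spread over the clusters, which was not traced to any single cluster. The cytoskeleton list stood at −0.41 (percentile 0) with Actn1 at −1.24 and Actb at −1.32, and the Hippo list at −0.24 (percentile 0.11). Art1, a muscle ADP-ribosyltransferase gene, was 10.1-fold higher, and Kcnj3, Asb14, Zfp36l1, Neb and Lrrc2 were higher by 2.16, 1.64, 1.60, 1.58 and 1.56. Kcnj3 was among the 10 top genes of the atrial cluster, which held 79 nuclei in YAP5SA on chow and 186 on HFD. Acta2 stood at −2.02, Nppa at −1.76, Nppb at −1.71, Meg3 at −1.69, Baiap2l1 at −1.48 and Gadd45g at −1.42.

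The DNA replication and G2/M lists were low here too, at −0.45 (percentile 0.06) and −0.49 (percentile 0). Lipid and cholesterol synthesis genes were low at −0.50 (percentile 0), glycolysis genes at −0.25 (percentile 0.02), mitochondrially encoded transcripts at −0.25 (percentile 0.53), fetal genes at −0.23 (percentile 0.51), growth factor genes at −0.15 (percentile 0.88, but 0.16 at a mean CPM of at least 50), hypoxia genes at −0.27 (percentile 0.67) and immediate early genes at −0.33 (percentile 0.76). The other lists had medians of 0.17 for pentose phosphate, 0.01 for branched-chain amino acids, −0.25 for ketone body use, −0.01 for serine and one-carbon genes, −0.07 for the stress response, 0.22 for biogenesis and 0.13 for mitochondrial dynamics. The rest stood at 0.05 for cyclins, 0.11 for sarcomere, −0.02 for matrix, 0.06 for complement and 0.33 for p53 targets. At 2-fold, 335 genes were higher and 88 lower. The share of these that was higher, 79.2%, was 58.9% with TMM and 53.5% with DESeq2 scaling, which move the median log2 fold of all genes from 0.07 to −0.09 and −0.13. Under DESeq2 scaling the calcium handling median falls below 0.

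**Figure D5:**
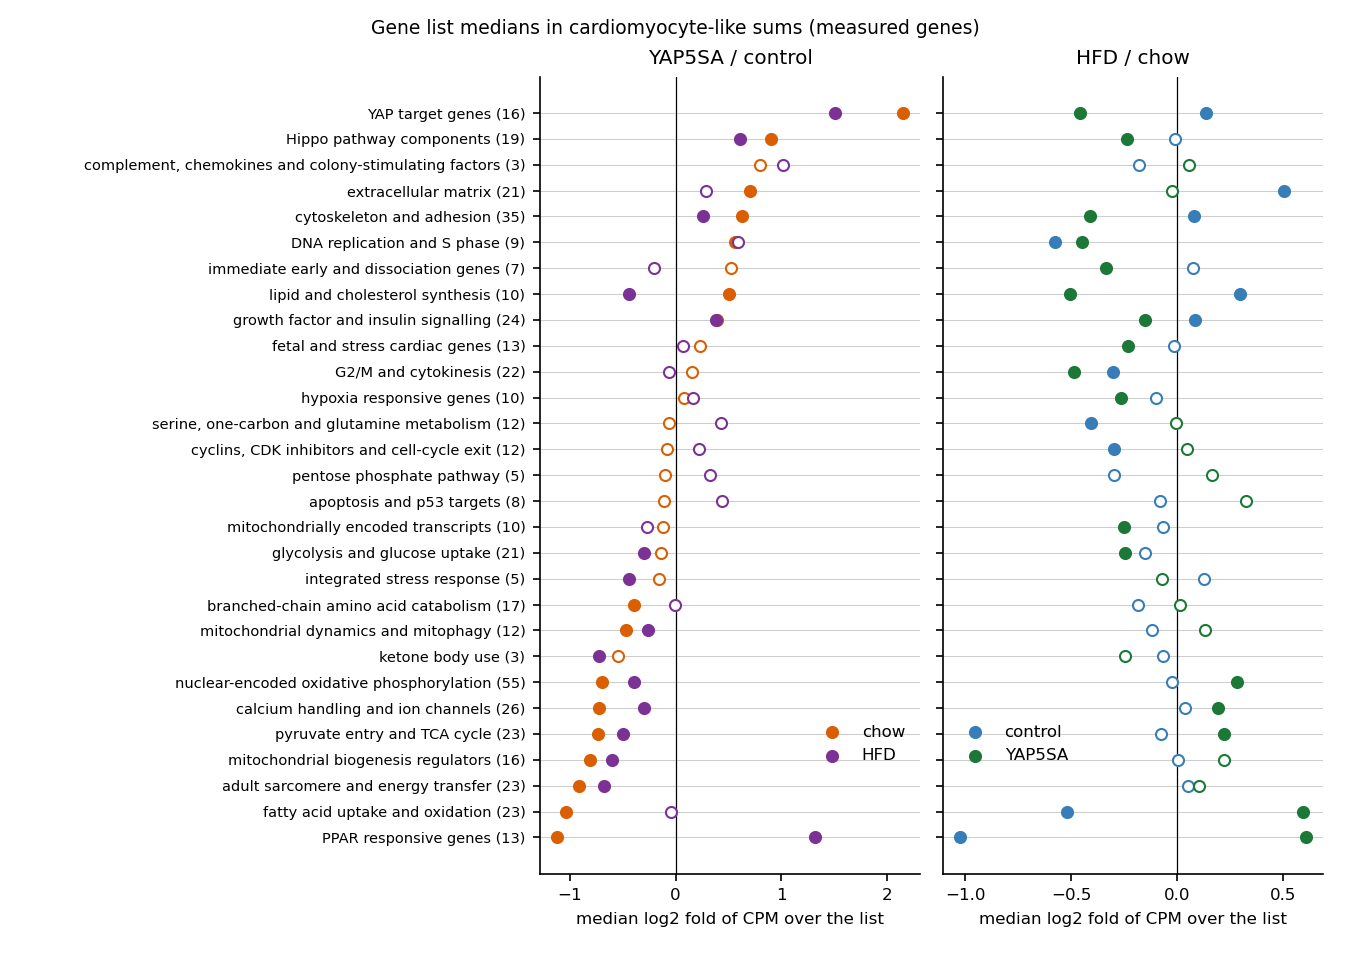
Median log2 fold of each gene list in cardiomyocyte-like sums for YAP5SA over control on each diet and for HFD over chow in control and in YAP5SA, with filled points where the median lay in either tail of those of matched random lists and open points elsewhere. PPAR responsive genes lie at −1.12 and 1.32 in the YAP5SA contrasts and at −1.02 and 0.61 in the diet contrasts.

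The diet folds in control and in YAP5SA, which share no library, had a Pearson r of −0.082 and a Spearman rho of −0.047 across genes. At 1.5-fold, 69 genes were higher on HFD in both and 33 lower in both. At 2-fold, 18 were higher in both, 2 were lower in both and 23 lay in opposite directions. Each diet contrast does share a library with each YAP5SA contrast: control on HFD, for example, enters both the diet contrast in control and the YAP5SA contrast on HFD.

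Markers of other cell types in the cardiomyocyte-like sums lay in mixed directions in the YAP5SA contrasts. Pericyte markers had medians of −1.58 and −0.73 over 3 members, and 1 of 7 fell and 0 rose (3 and 0 adjusted over the list alone). In the diet contrasts these medians were −0.12 in control and 0.57 in YAP5SA, and that of fibroblast markers in YAP5SA was 0.38. Of 9 endothelial markers 1 rose, namely Flt1 (1 adjusted over the list alone), and 1 of 2 at the CPM floor was higher on both diets. Of 6 smooth muscle markers Myh11 and Tagln rose (2 adjusted over the list alone), and of 6 epicardial markers Wt1 rose (1 adjusted over the list alone). Of 3 lymphocyte markers 0 passed (1 rose adjusted over the list alone), and 0 of 2 adipocyte and 0 of 4 erythroid markers did, over all genes or adjusted over the list alone. The 2 erythroid markers at the CPM floor were nevertheless at least 1.5-fold lower in YAP5SA on both diets. The erythroid list summed to 278, 162, 204 and 77.6 CPM. Of 3 skeletal muscle markers Myh1 and Myh2 rose and Ckm fell (the same adjusted over the list alone). Of 15 immediate early genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Junb up and Jun down, and the list's medians were 0.53 and −0.21. These symbols, other than Ckm, Jun and Junb, were chosen after their values were seen.

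The last question was whether cells that the cardiac promoter should not drive differed as well. Fibroblast-like nuclei of the YAP5SA hearts carried far more cell-cycle transcripts. The G2/M list had a median log2 fold of 1.44 on chow and 1.85 on HFD, with 32 of 33 genes higher on both diets, and the DNA replication list 0.83 and 1.28, with 22 of 29. After thinning, 10.5%, 29.7%, 8.39% and 29.0% of fibroblast-like nuclei held UMIs of at least 2 G2/M genes, against 29.0%, 48.1%, 27.8% and 46.2% without thinning at median depths of 4095, 3665, 4225 and 3785.5 UMIs. Col8a1, a short-chain collagen gene, stood at 265, 2019, 239 and 1812 CPM, a log2 fold of 2.93 and 2.92. The chemokine gene Ccl2 was higher by 4.63 and 2.40, the mechanosensitive channel gene Piezo2 by 2.66 and 2.36 and Etv4 by 2.33 and 2.45. Kcnk13, Pcsk6, Nkain2 and Hs6st3 stood at −2.36, −2.85, −2.06 and −2.003 on chow and at −2.70, −2.17, −2.83 and −2.89 on HFD. Tnc, a matrix gene of remodelling tissue, was higher by 3.39 and 1.51 and Ccn2 by 3.45 and 2.46, while the elastin gene Eln stood at −1.21 and −1.60.

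Of 10018 genes in fibroblast-like sums, 558 were 2-fold higher and 351 lower on chow and 764 and 256 on HFD. On both diets 337 were higher and 144 lower, where 42.6 and 8.97 would be shared if independent, and r across genes was 0.649. Complement, chemokine and colony-stimulating factor genes had medians of 0.43 and 1.22, the cytoskeleton list 0.52 and 0.03, the YAP target list 0.23 and 0.04, the matrix list −0.12 and −0.15, and PPAR responsive genes −0.31 and 0.65. Clusters 0 and 3 held 86.0% and 87.9% of the fibroblast-like nuclei of the control libraries, and clusters 2 and 18 held 81.7% and 77.9% of those of YAP5SA on chow and on HFD.

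Endothelial-like nuclei went the other way in the cell cycle. The G2/M list had medians of −1.25 and −1.01, with 22 of 30 genes lower on both diets, and the DNA replication list −0.64 and −0.42, with 7 of 24. The spindle motor gene Kif11 stood at −1.44 and −1.74, Cit, a cytokinesis kinase gene, at −1.50 and −1.08, Neil3 at −1.67 and −1.57 and the endothelial transcription factor gene Meox2 at −1.17 and −1.18. Mctp1 was higher by 2.30 and 1.72, Rasa4 by 1.70 and 2.23, Ctla2a by 1.56 and 1.54 and Rapgef4 by 1.44 and 1.86. Of 9733 genes, 338 were 2-fold higher and 274 lower on chow and 586 and 290 on HFD, with 109 higher and 95 lower on both (20.4 and 8.16 if independent) and r of 0.333 across genes. These sums held 385 to 611 nuclei per library. Without genes at a higher CPM in cardiomyocyte-like sums, 172 and 174 genes were lower.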

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

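Among the tests below, those of the animals' sex, of exchanged diet labels, of free RNA and of the amount of vector transcript were chosen only after the result was seen.

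Several gene lists moved in opposite directions in contrasts of the same kind, a difference that was not tested because each contrast holds 1 library per side. YAP5SA over control gave PPAR responsive genes a median log2 fold of −1.12 on chow and 1.32 on HFD, and lipid and cholesterol synthesis genes 0.50 and −0.44. HFD over chow gave PPAR responsive genes −1.02 in control and 0.61 in YAP5SA, and fatty acid uptake and oxidation genes −0.52 and 0.60. For lipid and cholesterol synthesis these values were 0.30 and −0.50, for YAP targets 0.14 and −0.46, for cytoskeleton and adhesion 0.0810 and −0.41, and for growth factor and insulin signalling 0.0854 and −0.15. The YAP5SA and diet contrasts share libraries, so each library, control on HFD among them, enters both kinds of opposite PPAR values. The growth factor median in YAP5SA turned to 0.16 at a mean CPM of at least 50, which removes its opposition. The added sequence nsp13 had 522 UMIs in YAP5SA on chow and 209 in YAP5SA on HFD, and the Y-linked gene Ddx3y had 4159 UMIs in YAP5SA on chow against at most 15 in any other library.

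YAP5SA on chow was the only male library, so sex and vector change together in the chow contrast, and sex and diet in the diet contrast in YAP5SA. The HFD contrast sets female against female, and 71.4% of the genes 2-fold apart on chow (940 of 1317, Y-linked genes aside) were at least 1.5-fold apart in the same direction there, against 31.7% of all genes in either direction. Sex is therefore excluded as the whole cause of the chow folds. It stays open for the genes that differed on chow alone and, untested, for every diet fold in YAP5SA.

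PPAR responsive genes were lower on HFD in control and higher on HFD in YAP5SA. Doublets or other cell types gathered in certain clusters are argued against for the control value. There, 6 of 6 clusters with at least 50 nuclei in both control libraries had a median below 0, and the median over clusters was −1.05. RNA of other cells spread over every cluster would enter each comparison alike, so this test cannot speak to it. In YAP5SA 8 of 9 clusters had a median above 0, but the median over clusters was 0.264, against 0.61 in the sums, so a change in cluster make-up stays open for part of the YAP5SA value. Cluster 10, with 8.70% of cardiomyocyte-like nuclei in YAP5SA on chow and 35.2% on HFD, had Pdk4 and Ucp3 among its 10 top genes. Clusters were thus drawn in part from PPAR responsive genes, so make-up and regulation of these genes cannot be separated here. Exchanged diet labels of the control libraries, of which only that of control on HFD has a conflicting treatment label, cannot be told apart from a biological difference, as the diet folds in control and YAP5SA had r of −0.060 over 8423 genes, between the bounds set for either answer. For a state of the whole animal that other cell types share, such as feeding before collection, PPAR genes were read in other classes. Their median was −0.438 over 7 genes in fibroblast-like and −0.142 over 6 genes in endothelial-like sums. By the bound set in advance, the endothelial-like value argues against this reading, while the fibroblast-like value lies between the bounds. With genes that free cardiomyocyte RNA could supply kept in, the fibroblast-like median was −0.388 over 10 genes (percentile 0.06). The endothelial-like median was then −0.201 over 7 genes (percentile 8.7). Txnip was lower in both classes, at −1.68 and −0.63, while Ucp2 stood at 0.614 and −0.0834. The endothelial-like value over 6 genes lies past the bound by less than 0.115, the standard error of their mean fold. In fibroblast-like sums this error was 0.274. Genes are not replicates, so that error does not measure the difference between animals, and the reading is left open. If the treatment labels hold instead of the titles, both control libraries were on chow and both YAP5SA libraries on HFD, which was not tested. Sex was the same in the control libraries but not in the YAP5SA libraries, so it stays open for the latter. An effect of diet that depends on YAP5SA is untested and stays open.

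The nsp13 UMIs were nearly confined to the YAP5SA libraries, and YAP targets had smaller folds on HFD. In each YAP5SA library, cardiomyocyte-like nuclei with an nsp13 UMI differed from depth-matched nuclei without one in the way YAP5SA differed from control on the other diet (r of 0.499 and 0.707 across genes), which is consistent with nsp13 UMIs coming from nuclei that carry the vector. Free RNA stays open for part of the counts, because thinned shares in other classes ranged from 0 to 0.751 of the cardiomyocyte-like share, the highest from 2 macrophage-like nuclei. Less vector transcript on HFD stays open too: nsp13 per 1e6 UMIs was 2.61 times lower on HFD (ratio 0.384, 95% interval 0.319 to 0.459), while the median YAP target log2 fold of HFD over chow within cluster 5 was −0.20, between the bounds set for either answer. Neither dose, sex nor diet is separated as a source of the smaller folds.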

How the results depend on the processing

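Leaving out cluster 5 and leaving out genes on the X and Y chromosomes were chosen only after the results were seen, and every alternative chosen before gave values. Of 136 counts of genes under the alternatives, 99 stayed within 1.5 times the reported count and 37 moved. Of 1704 list medians 1621 stayed within the spread of medians of random lists, 78 moved and 5 reversed. Of 5500 log2 folds of the named genes reported, 4020 stayed within the counting interval and 1480 moved. Of 1677 edgeR folds of these genes 1566 kept their side of the threshold, 62 passed it only under the alternative and 49 no longer passed. Of 216 shares 146 stayed and 70 moved, and of 26 edgeR counts 18 stayed and 8 moved. The YAP target list kept its direction in both YAP5SA contrasts under every alternative.

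The mark and the CPM floor set the counts by construction. At 1.5-fold, YAP5SA on chow had 1390 genes higher and 1607 lower, on HFD 1859 and 829, HFD in control 334 and 353 and HFD in YAP5SA 1069 and 412. At a mean CPM of at least 50 these were 284 and 222, 301 and 139, 41 and 16, and 92 and 27. With no floor they were 4599 and 3345, 6392 and 2360, 2569 and 2479, and 4564 and 1900. At a mean CPM of at least 50 the YAP target median for HFD in YAP5SA was −0.74, and 3 medians reversed, namely matrix for HFD in control (−0.21) and growth factors for YAP5SA on HFD (−0.0253) and for HFD in YAP5SA (0.16). With no floor the YAP target median on HFD was 1.09 and the stress response median on HFD reversed to 0.69. Both changes come with other members entering or leaving the lists.

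With TMM scaling, 483 genes were lower in YAP5SA on HFD, and HFD in YAP5SA had 222 higher and 155 lower. With DESeq2 size factors these were 541, 204 and 177, the fatty acid median for HFD in YAP5SA was 0.40, and that of calcium handling reversed to −0.00408. After thinning to 1000 UMIs, 144 genes were higher and 130 lower for HFD in control.

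The stricter nucleus filter and a resolution of 2 left 53.4% and 53.7% of the nuclei of cluster 5 unnamed. With the filter, 361 genes were lower on chow and YAP target medians were 1.48 on chow and 0.98 on HFD. With the resolution of 2 these were 364, 1.48 and 0.99. With cluster 5 left out, 433 genes were higher and 234 lower on chow, YAP target medians were 1.24 and 0.73, and the fatty acid median on chow was −0.63. A part of the YAP5SA folds on both diets therefore rests on that cluster, which holds no control nuclei. Cardiomyocyte-like shares with the filter were 70.7% in control on chow, 58.0% in YAP5SA on chow, 49.7% in control on HFD and 52.6% in YAP5SA on HFD. With the resolution of 2 they were 47.6% in YAP5SA on chow and 46.6% in YAP5SA on HFD. With doublets kept they were 56.8%, 56.1%, 35.9% and 47.6%.

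In the edgeR test, 787 genes rose and 340 fell with the filter, 751 and 353 with the resolution of 2, and 1984 and 1206 with no filter on low counts. The DESeq2 Wald test gave 1149 that fell. Leaving out each library in turn, with the lone library assumed to vary like the others, gave 950 to 1575 that rose and 362 to 972 that fell. The cause of these moves was not tested.

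The share of cardiomyocyte-like nuclei with G2/M genes was 18.2%, 24.1%, 16.7% and 20.03% for at least 1 gene, 3.79%, 6.34%, 2.79% and 3.66% for at least 3, 7.70%, 14.1%, 6.58% and 9.25% at 2000 UMIs, and 21.5%, 27.9%, 22.3% and 24.7% without thinning. YAP5SA on chow was highest under each, and the order of the control libraries turned without thinning. In endothelial-like sums, 172 and 174 genes were lower without genes higher in cardiomyocyte-like sums, where fewer genes are compared. With 1 library per group, depth limits the genes near the CPM floor, and no alternative replaces a replicate.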

Other observations

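The test at the end of this part was written before its result was seen, while cluster 4 was looked at only afterwards. Among the cell types not compared above, G2/M transcripts were more frequent in macrophage-like and less frequent in pericyte-like nuclei of the YAP5SA libraries. After thinning to 1000 UMIs, 11.01% (5.82% to 18.4%) of macrophage-like nuclei in control on chow, 29.6% (23.5% to 36.4%) in YAP5SA on chow, 21.3% (15.9% to 27.6%) in control on HFD and 38.4% (34.2% to 42.7%) in YAP5SA on HFD held UMIs of at least 2 G2/M genes. For pericyte-like nuclei these shares were 23.2% (16.9% to 30.4%), 10.3% (5.61% to 17.0%), 21.1% (16.02% to 27.0%) and 6.17% (3.50% to 9.98%). The pericyte-like intervals overlapped slightly on chow, which does not show that these shares were equal. Endocardial-like nuclei had 8.15% (4.98% to 12.4%), 5.95% (4.20% to 8.14%), 12.7% (10.08% to 15.6%) and 6.29% (4.49% to 8.53%), with intervals apart on HFD alone. Epicardial-like nuclei had 15.5% (9.27% to 23.6%), 7.05% (4.41% to 10.6%), 8.17% (5.36% to 11.8%) and 5.14% (2.38% to 9.54%), with overlapping intervals on both diets. Without thinning, the shares were 23.9%, 41.5%, 33.5% and 52.7% for macrophage-like and 40.4%, 26.4%, 39.7% and 17.1% for pericyte-like nuclei, at median depths of 2755, 2667.5, 2558 and 2924 UMIs and of 3520, 2546, 3633 and 2428.5 UMIs. The macrophage-like class of YAP5SA on chow held 212 nuclei here but 107 with the looser nucleus filter. Its G2/M share was not read under that filter.

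Some cardiomyocyte genes moved with HFD in the same direction in control and YAP5SA, a selection made after their values were seen. The potassium channel genes Kcnd2 and Kcnj3 were higher by 1.19 and 1.26 in control and by 1.47 and 2.16 in YAP5SA, and Lpin1 by 2.06 and 1.13. Kcnj3 was among the 10 top genes of the atrial cluster, which is part of the sums. On chow and on HFD that cluster held 14 and 84 nuclei in control and 79 and 186 in YAP5SA. The fetal troponin gene Tnni1 stood at −1.70 and −1.09, the replication genes Mcm6 and Dtl at −0.86 and −1.04 in control and −0.95 and −0.96 in YAP5SA, and the insulin-like growth factor receptor gene Igf1r at −0.73 and −0.66.

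The G2/M and DNA replication lists were lower on HFD than on chow in both control and YAP5SA, and it was asked whether fewer cardiomyocytes cycled on HFD. At equal depth, the share of cardiomyocyte-like nuclei with G2/M genes on HFD was 0.790 of that on chow in control, with overlapping intervals, and 0.599 in YAP5SA, with intervals apart. The test alone does not decide between fewer cycling nuclei and less free RNA of cycling cells. Cluster 4, which is itself drawn from G2/M genes, held 2.39% of cardiomyocyte-like nuclei in control on HFD against 3.36% on chow, with overlapping intervals, and 3.16% against 5.60% in YAP5SA, with intervals apart. After thinning, 97.48% or more of the nuclei of cluster 4 held such UMIs in every library. Outside it, 1.67% did in control on HFD against 1.79% on chow, with overlapping intervals. In YAP5SA the outside shares were 2.38% against 3.69%, with intervals apart. The clustering itself set nuclei with such UMIs apart, so these values cannot decide how much came from free RNA. Less free RNA and fewer cycling nuclei both stay open, and 1 library per group leaves the difference between animals unknown.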
